A study of Mus musculus with 9 samples.

How the data were processed

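Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in 9 libraries of mouse mammary epithelial cells. Per the labels, basal cells, luminal cells positive for the oestrogen receptor (ER+ luminal) and luminal cells negative for it (ER- luminal) were isolated by FACS at puberty, in adults and in mid pregnancy. Each of the 3 cell types at each of the 3 stages had 1 library. Per the labels, the molecule is total RNA and the library source transcriptomic, while their protocols and the series title describe ATAC-seq, as which the data were read. Per the labels' protocols, nuclei of sorted cells were tagged with Tn5 and libraries were amplified by PCR and size selected.

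Per the submitters' processing notes, the tools included Bowtie2 2.2.6, SAMtools, Picard and MACS2 2.1.0.20151222, and the genome build was GRCm38, also called mm10. Whether read positions were shifted for the Tn5 cut, and how peaks were merged, is not given in the sources used here. The deposited table holds 1 signal value per region and library for 124860 regions. The regions carry running numbers up to 124862, of which 2 are not listed. Its column names carry the stage and, for luminal cells, the letter p or m after the receptor, which were read as plus and minus. The table pairs the regions with neither coordinates nor gene names, so the planned gene lists, motif search and promoter share were not run, and regions are named by their number only.

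The unit of the deposited values is not given in the sources used here. Within a tolerance of 0.02 reads, 100% of the values in each library were whole multiples of 1 step, from 0.526 in the ER+ luminal puberty library to 2.199 in the basal pregnancy library. The steps were read as the value of 1 read, which gave 2186941 to 11328189 reads in regions per library. The median ratio of a library to the geometric mean over libraries was 1.0188 in each of the 9 libraries, as in counts divided by median-of-ratios size factors. The deposited signal was therefore compared between libraries as it stands, and the planned median-of-ratios scaling was void because it moved no value. A count of 0 in a library allows up to 3 reads, worth 1.58 to 6.60 units. For a fold against a group with no read in its 3 libraries, the bound given is the lower limit of the exact 95% counting interval of the reads summed over each group. This lies below the fold against 3 reads summed over the group. Intervals and floors cover counting error only, since PCR copies are not independent molecules.

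Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, in an additive model of cell type and stage over the 9 libraries, with a trend in the prior variance. Regions with a Benjamini-Hochberg adjusted p under 0.05 over the 124860 regions were called, with no filter on low values. Fold changes on this scale understate the change of low regions. The model leaves 4 residual degrees of freedom, and its error is the departure of single libraries from additive effects of cell type and stage. It holds any real difference in how the cell types respond to a stage, so p-values measure that spread and not a spread between animals of one cell type and stage. Stage differences within 1 cell type had no replicate and no test, and regions that differed at least 4-fold were counted. The test, the comparisons, the rule for named regions and most alternatives were set before the data were examined.

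The rule for named regions took called regions with the same sign in the 3 blocks and a mean in the higher group at or above 17.88, the median of all region means, and ranked them by log2 difference. Without names or coordinates only the first in each direction is given, which is fewer than was set beforehand. Both of the 2 called between adult and puberty are given. Mean values are given with the SD over the 3 libraries of a group. Region sets that were open or closed in 1 cell type at puberty were defined after the data had been seen, as differing at least 4-fold from both other cell types in the puberty libraries. Adult and pregnancy values played no part in that choice.

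The model was tested on simulated data for 124860 regions with 200 changed regions and a common dispersion of 0.123 (a coefficient of variation of 35.1%). The changed regions were drawn only from those at or above the median of all region means. The recovery below therefore does not cover regions under that median. For the ER+ luminal against basal comparison limma recovered 0% of 2-fold, 50% of 4-fold, 88% of 8-fold and 98% of 16-fold changes with 5 false calls. For pregnancy against adult it recovered 4%, 50%, 94% and 96% of 50 regions at each fold, with 12 false calls. The F test on the same simulated data gave 20 false calls for any stage difference and 4 for any cell type difference. Simulated means held no departure from additive effects of cell type and stage. The runs therefore do not measure false calls where a real library departs from them. In 20 draws of unchanged libraries the 6 comparisons gave at most 1 call.

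Alternatives set beforehand were pseudocounts of 4 and 0.25, leaving out the lowest 25% of regions by mean, quantile normalization, a 2-fold minimum, the other factor left out of the model, library weights, no trend in the variance, the 6 compared libraries alone and each library left out in turn. Alternatives added after the data had been seen were edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered whole reads, reads thinned to the depth of the smallest library, and fits without the pregnancy libraries or without the ER+ luminal libraries. DESeq2 gave no adjusted p for 26629 regions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.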

Results

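Accessible chromatin was profiled in 3 sorted cell types of the mouse mammary gland at 3 stages, with 1 library for each of the 9 combinations. Basal cells form the outer, contractile layer of the ducts, and luminal cells line the lumen. The ER+ luminal cells carry the oestrogen receptor and the ER- luminal cells do not. Depth in the 124860 regions was 7508229, 8525184 and 11328189 reads in the basal, ER- luminal and ER+ luminal puberty libraries. It was 7976287, 7375760 and 6679907 reads in the adult and 2186941, 3418164 and 2641254 reads in the pregnancy libraries, in the same order. The deepest library thus held 5.18 times the reads of the shallowest. The pregnancy libraries also had a narrower range of values, with a ratio of the 90th to the 10th percentile of 23.0, 35.0 and 16.3, against 39.7 to 88.2 in the other 6 libraries.

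Cell type accounted for more of the variance in accessibility than stage did. It took 57.4% of the variance of log2 values over regions and libraries, stage took 19.4%, and the remaining 23.1% belonged to neither alone. These shares are raw sums of squares, not corrected for degrees of freedom. Each therefore includes a part that noise alone would give. Across regions, which are not independent replicates, the ER+ luminal puberty and adult libraries had a Pearson r of 0.911. The mean r between stages was 0.868 in ER- luminal and 0.85 in basal cells. Within a stage it was 0.76 between ER- luminal and basal cells, 0.679 between the luminal types and 0.592 between ER+ luminal and basal cells. The ER+ luminal pregnancy library was closest to ER- luminal cells, with an r of 0.768, 0.744 and 0.732 with their pregnancy, puberty and adult libraries. Its r was 0.708 and 0.699 with the puberty and adult libraries of its own cell type, and 0.718, 0.676 and 0.695 with basal puberty, adult and pregnancy libraries.

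**Figure D1:**
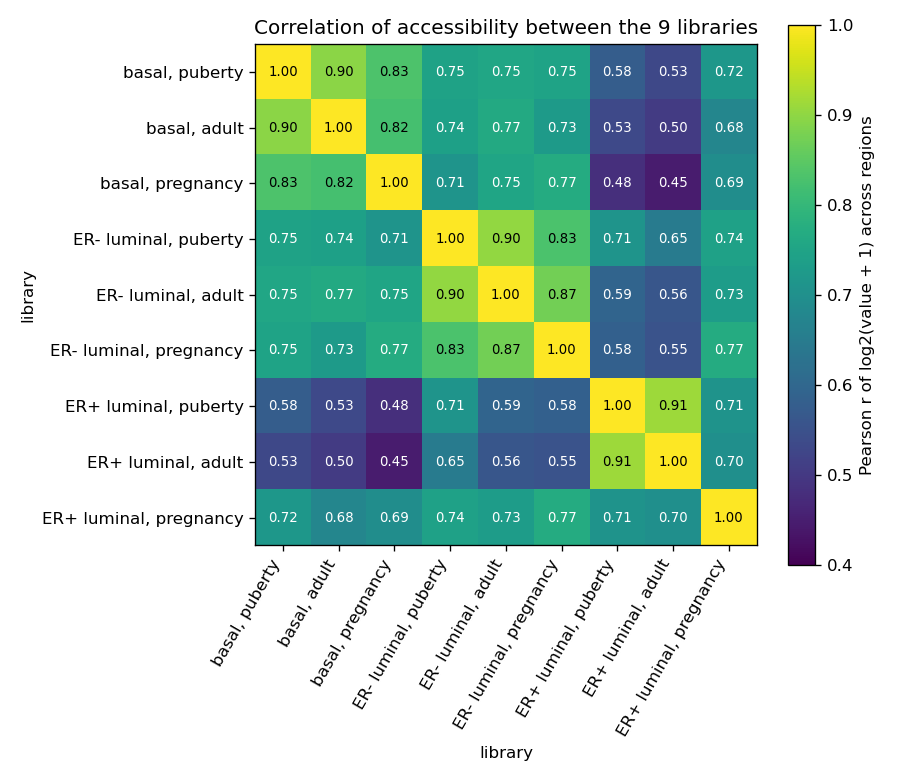
Pearson r of log2(value + 1) across 124860 regions for each pair of the 9 libraries, ordered on both axes by cell type and then stage, with colour from 0.4 to 1. The ER+ luminal puberty and adult libraries pair at 0.911, while the ER+ luminal pregnancy library reaches 0.768 with ER- luminal cells in pregnancy and 0.744 with those at puberty.

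ER+ luminal chromatin was set against ER- luminal chromatin to find the regions that separate the luminal cell types. Of the 124860 regions, 17197 were more accessible in ER+ luminal cells, with a median log2 difference of 2.15, and 15379 were less accessible, with a median of -1.98. The differences were seen at each stage and were smaller in pregnancy. The regions called higher had median log2 differences of 2.26 at puberty, 2.79 in adults and 1.33 in pregnancy. Region merged115340 had a mean of 62.5 ± 34.6 in ER+ luminal and 1.46 ± 1.43 in ER- luminal cells (SD, n = 3; log2 difference 4.72, SE 0.63, limma adjusted p = 4.64e-05). Region merged32629 went the other way, with 2.61 ± 3.65 against 56.3 ± 8.4 (SD, n = 3; log2 difference -4.50, SE 0.60, limma adjusted p = 4.78e-05). Without the ER- luminal puberty, ER+ luminal puberty, ER- luminal adult or ER+ luminal adult library the 32576 calls became 15223, 15573, 12326 and 13302. They rose to 47963 without the ER+ luminal pregnancy library and to 48652 in the puberty and adult libraries alone. Library weights gave 59623 calls, and reads thinned to equal depth gave 20739, or 20485 with quantile normalization.

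ER+ luminal and basal cells differed at the most regions of the 3 pairs of cell types when all 9 libraries were used. In ER+ luminal cells 21364 regions were more accessible, with a median log2 difference of 1.98, and 23282 were less accessible, with a median of -2.19. Together these made up 35.76% of all regions. Region merged31512 was nearly closed in ER+ luminal cells, with a mean of 0.285 ± 0.494 from 1 read against 73.9 ± 5.71 in basal cells (SD, n = 3; log2 difference -5.93, SE 0.63, limma adjusted p = 2.15e-06). The ratio of basal to ER+ luminal reads was 267, with a 95% counting interval of 47.5 to 10600. Region merged33370 was open in ER+ luminal cells, with 89.4 ± 54.7 against 3.95 ± 4.41 (SD, n = 3; log2 difference 4.46, SE 0.59, limma adjusted p = 1.21e-05). Without the basal puberty, ER+ luminal puberty, basal adult or ER+ luminal adult library the 44646 calls became 27898, 25569, 23886 and 23589. More regions were then called between the luminal types without the basal puberty or basal adult library, 31934 and 29884, although that pair lost no library. Between ER+ luminal and basal cells the calls rose to 58764 without the ER+ luminal pregnancy library. They rose to 62075 in the puberty and adult libraries alone.

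ER- luminal and basal cells differed at the fewest regions of the 3 pairs when all 9 libraries were used. In ER- luminal cells 7171 regions were more accessible, with a median log2 difference of 1.73, and 10339 were less accessible, with a median of -2.24. The sign was the same at the 3 stages in 99.42% of the called regions. Region merged105636 had a mean of 61.6 ± 8.69 in ER- luminal and 4.98 ± 5.22 in basal cells (SD, n = 3; log2 difference 3.73, SE 0.60, limma adjusted p = 0.000329). Region merged7017 had 2.24 ± 1.32 against 128 ± 27.4 (SD, n = 3; log2 difference -5.40, SE 0.64, limma adjusted p = 4e-05). Without the basal puberty, ER- luminal puberty, basal adult, ER- luminal adult or ER+ luminal pregnancy library the 17510 calls became 6237, 6107, 5295, 8275 and 27161. They became 9366 with stage left out of the model, 28626 with library weights and 8466 without a variance trend. The 6 libraries alone gave 27001 calls, the puberty and adult libraries alone 25778, and equal depth 10515. Without the ER+ luminal puberty or adult library this pair had 16857 and 19298 calls, more than the 15573 and 13302 between the luminal types, which alone lost a library. In the pregnancy libraries alone 11725 regions differed at least 4-fold in this pair and 10707 between the luminal types.

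**Figure D2:**
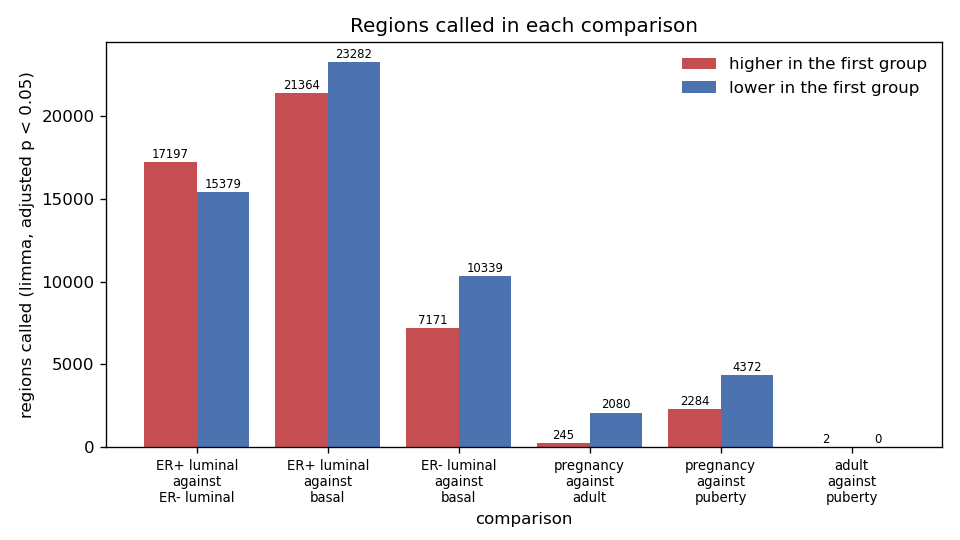
Regions called by limma at an adjusted p under 0.05 in each of the 6 comparisons, as bars that start at 0, with regions higher in the first-named group in red and lower in blue. Calls run from 17510 to 44646 between cell types and from 2 to 6656 between stages.

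Each cell type had regions that set it apart from both others. In ER+ luminal cells 11721 regions were more accessible than in either other type and 7928 were less accessible. Basal cells had 8307 and 2982 such regions, and ER- luminal cells had 2870 and 1006. Independent lists of the same sizes would share 2942.5 and 2867.6 regions for ER+ luminal, 1927.9 and 1227 for basal and 883.3 and 1424 for ER- luminal cells, while 20 simulations of unchanged libraries called 0 regions in either list and so give no overlap to compare with. The 1006 regions less accessible in ER- luminal cells thus lay below the number for independent lists, and the other 5 classes above it. Both lists of a class use the same 3 libraries, so part of an excess may come from them.

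Pregnancy and adult glands were compared for changes shared by the 3 cell types. In pregnancy 2080 regions were less accessible, with a median log2 difference of -1.52, and 245 were more accessible, with a median of 2.46. Regions that lost accessibility were bright, with a median value of 95 over the libraries, and 2.4% of them lay below the median region. Of the regions called higher, 33.9% lay below it. All regions at or above the median, called or not, had median log2 changes of -0.28 in basal, -0.09 in ER- luminal and -0.21 in ER+ luminal cells. Brightness is thus not particular to the called regions as a trait of loss. The most changed region named in each direction was nearly all-or-none. Both are among the regions set apart in the 3 pregnancy libraries, for which a DNA difference of the mice is a candidate explanation below. Region merged15145 had a mean of 425 ± 36.9 in pregnancy and 2.05 ± 1.49 in adults (SD, n = 3; log2 difference 7.23, SE 0.58, limma adjusted p = 3.25e-07). Region merged31812 had no read in the pregnancy libraries and a mean of 38.8 ± 14.1 in adults, and was at least 17.5-fold lower, the lower limit of its 95% counting interval (SE of the log2 difference 0.57, n = 3, limma adjusted p = 1.78e-05).

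The number of calls between pregnancy and adult, 2325, depended on single libraries and on the model. Without the basal adult library there were 56 (27 higher and 29 lower, so that 48.2% were higher), without ER+ luminal adult 412, without ER- luminal pregnancy 1033 and without ER- luminal puberty 1236, while 14 (13 of them higher) were called with cell type left out of the model and 26 (20 higher) without a variance trend. Quantile normalization called 344 higher and 874 lower, so that 28.2% were higher against 10.5% in the deposited values, and equal depth called 99 higher and 509 lower, or 283 and 843 with a pseudocount of 1 read. A pseudocount of 0.25 gave 1469 calls, edgeR on the recovered reads 1003, and the ER- luminal and basal libraries alone 857.

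With all 9 libraries, more regions were called between pregnancy and puberty than between pregnancy and adulthood. The order turned without the ER- luminal puberty library, with 80 against 1236 calls, and without ER+ luminal puberty, with 327 against 1957. A left-out puberty library takes a sample from the first comparison alone, so these counts come from unlike numbers of libraries. In pregnancy 4372 regions were less accessible, with a median log2 difference of -1.24, and 2284 were more accessible, with a median of 2.30. Regions called higher had median log2 differences of 1.51 in basal, 2.14 in ER- luminal and 3.08 in ER+ luminal cells. Against both earlier stages, 150 regions were higher and 1585 lower in pregnancy, where independent lists would share 4.5 and 72.8. In 20 simulations of unchanged libraries each list held at most 1 region, which gives no overlap to compare with. Both lists use the same 3 pregnancy libraries, so part of the excess may come from them. Region merged15145 rose here too, with a mean of 0.703 ± 0.806 at puberty from 3 reads, a ratio of 642 with a 95% counting interval of 219 to 3120 (log2 difference 8.07, SE 0.58, n = 3, limma adjusted p = 1.73e-08). Region merged31812, with no read in pregnancy, had a mean of 38.2 ± 13.9 at puberty and was at least 17.8-fold lower, the lower limit of its 95% counting interval (SE of the log2 difference 0.57, n = 3, limma adjusted p = 1.7e-05).

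The 6656 calls between pregnancy and puberty became 80 without the ER- luminal puberty library, 327 without ER+ luminal puberty, 3480 without ER- luminal pregnancy and 3388 without ER+ luminal pregnancy. They became 22 (19 of them higher) with cell type left out of the model, 30 (24 higher) without a variance trend, 4378 with a pseudocount of 0.25 and 1413 in the ER- luminal and basal libraries alone. The share called higher was 34.3% in the deposited values, 47.3% of 2835 calls after quantile normalization, 43.0% of 1791 at equal depth and 52.5% of 3508 at equal depth with a pseudocount of 1 read.

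Few changes shared by the cell types were called between adult and pubertal glands. Limma called 2 regions higher in adults and 0 lower, while 5776 regions had an unadjusted p under 0.05. On the recovered reads edgeR also called 2 higher and 0 lower, and DESeq2 called 8 higher and 2 lower. Region merged642 had a mean of 2890 ± 487 in adults and 587 ± 25.6 at puberty (SD, n = 3; log2 difference 2.28, SE 0.16, limma adjusted p = 7.17e-08). Region merged82046 had 144 ± 25.0 against 15.8 ± 6.37 (SD, n = 3; log2 difference 3.16, SE 0.42, limma adjusted p = 0.00653). In the basal, ER- luminal and ER+ luminal pregnancy libraries merged82046 had 13.2, 6.067 and 6.78, so it was high in adults alone. There merged642 had 4284, 9495 and 6516. Both regions differed by stage in every cell type. Whether a difference between the mice of each stage or a change of the gland gave these values was not tested. Without any 1 of 5 puberty and adult libraries (all but basal puberty) 1 region was called, without the ER+ luminal pregnancy library 13, and with library weights 360.

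Within 1 cell type, where no replicate allowed a test, the ER+ luminal pregnancy library stood furthest from the earlier stages. From adult to pregnancy 22145 regions differed at least 4-fold in ER+ luminal, 10327 in basal and 6279 in ER- luminal cells. More of them were higher than lower in pregnancy, 13802 against 8343, 6456 against 3871 and 4356 against 1923, unlike the calls shared by the cell types. After quantile normalization more were lower in each cell type, 10000 against 9108, 5102 against 4158 and 3228 against 2947. From puberty to adult the numbers were 4655, 5122 and 4609. These counts depend on low values: with a pseudocount of 4 the adult to pregnancy counts were 8337, 2088 and 679. At equal depth they were 26843, 17845 and 13207, and those from puberty to adult 13375, 14374 and 15078, so that in ER- luminal cells the order of the stage steps turned.

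The regions more open in 1 cell type at puberty stood out in adults as well, and less so in pregnancy. The 8774 regions at least 4-fold more open in pubertal ER+ luminal cells than in both other types exceeded them by a median log2 difference of 2.81 in adults and 1.09 in pregnancy. Their mean value in ER+ luminal cells was 64.3 in adults and 23.7 in pregnancy, a ratio of 0.37. The 6179 regions closed in pubertal ER+ luminal cells had means there of 4.6 and 17.9, and median log2 differences from the other types of -2.65 in adults and -0.88 in pregnancy. The 8131 basal-open regions stood out by 2.75 in adults and 1.52 in pregnancy, and the 2719 ER- luminal-open regions by 2.40 and 0.95. The 2571 basal-closed regions differed from the other types by -1.51 in adults, with 23.6% at least 4-fold lower, and by -0.64 in pregnancy. The 1896 ER- luminal-closed regions differed by -1.25 in adults, with 24% at least 4-fold lower, and by -0.55 in pregnancy. The sets were chosen on the puberty values, where the ER- luminal-closed regions had a median of 0.7 in ER- luminal cells, about 1 read, so a smaller difference at the later stages than at puberty is partly due to the choice. The 10755 regions of similar, high value in the 3 puberty libraries had a pregnancy to adult ratio of 0.83 in ER+ luminal, 0.93 in ER- luminal and 0.64 in basal cells. Each of these values comes from single libraries and has no replicate check.

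**Figure D3:**
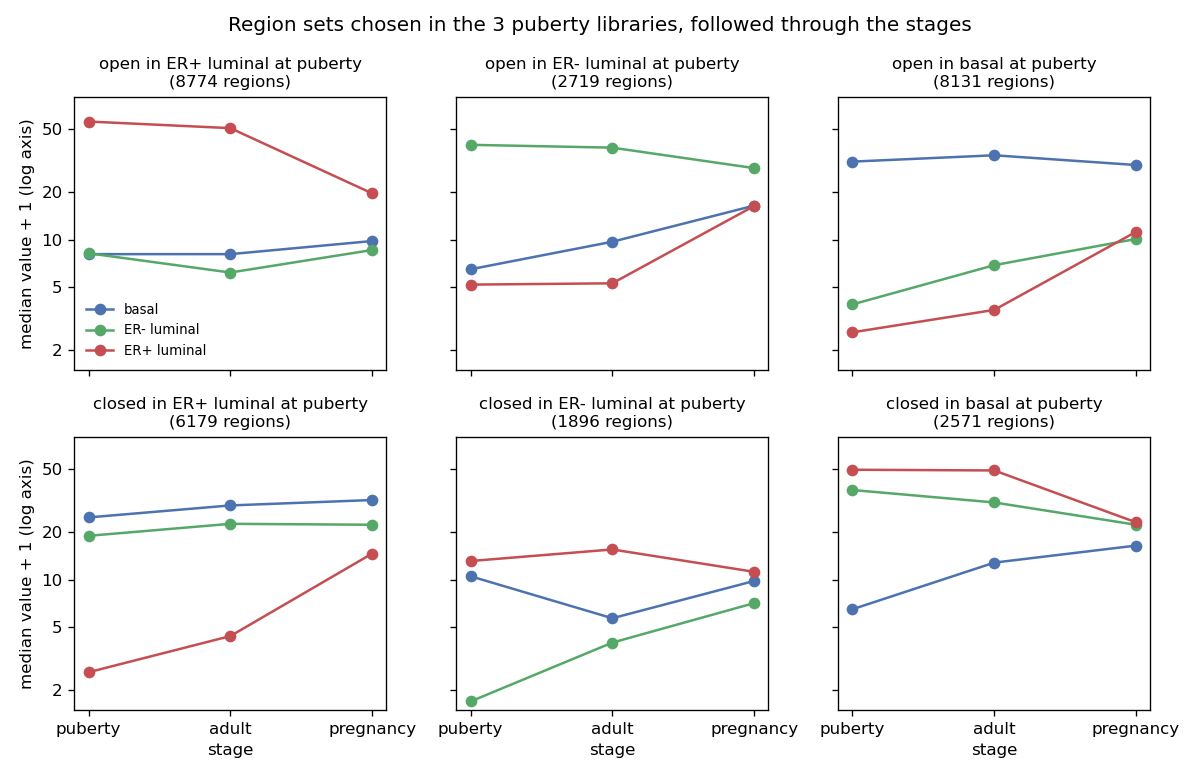
Median value + 1 (log axis) of 6 sets of regions in the basal, ER- luminal and ER+ luminal library of each stage, with 1 panel per set and 1 line per cell type. In the 8774 regions open in pubertal ER+ luminal cells, the ER+ luminal median goes from 54.7 at puberty and 49.6 in adults to 18.6 in pregnancy, before 1 is added.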

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

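The region sets followed here, and the tests of depth, background, value range and neighbouring regions, were chosen after the results had been seen; the test of mixed cells on left-out sets and the splits of the libraries were set before their results were seen, the former after a regression over all regions had already pointed to a mixed profile. A check of the mixed-cell sum with its weights rescaled to a total of 1 was also added after its result was known. In 6 sets of regions chosen at puberty, the medians of a pair of cell types had opposite signs from adult to pregnancy. For each set the pair furthest apart is given, and the differences were not tested, because each median comes from 1 library per stage. In the ER+ luminal-open set the median log2 change was -1.30 in ER+ luminal and 0.56 in ER- luminal cells, 1.86 apart. In the ER+ luminal-closed set it was 1.85 in ER+ luminal and -0.03 in ER- luminal cells, 1.88 apart, although the latter hardly moved (quartiles -0.56 to 0.48). In the ER- luminal-open set it was 1.49 in ER+ luminal and -0.38 in ER- luminal cells, 1.87 apart, and in the ER- luminal-closed set 0.70 in ER- luminal and -0.45 in ER+ luminal cells, 1.15 apart. In the basal-open set it was 1.54 in ER+ luminal and -0.20 in basal cells, 1.74 apart, and in the basal-closed set 0.18 in basal and -1.04 in ER+ luminal cells, 1.22 apart.

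The ER+ luminal pregnancy library lost most of the pubertal ER+ luminal signature. With each library thinned to the smallest, the ER+ luminal-open set stood out by 2.98 in adults against 1.17 in pregnancy. Sampling fewer reads thus did not shrink the adult difference. Random thinning hardly moves the expected ratio of bright regions whatever the cause, and does not equalise library quality. These values therefore cannot decide whether depth is a cause in other ways. Even background is opposed by the ER+ luminal-open mean falling to 0.37 of its adult value, while shared regions kept 0.83. Cells of the other 2 types in the sort stay open: a sum of the adult ER+ luminal and pregnancy ER- luminal and basal profiles with weights of 0.289, 0.276 and 0.22, solved on the 3 open sets, came within 1.22-fold of the mean of each of 4 left-out sets, but the weights total 0.785, and rescaled to a total of 1 they missed a set by 1.46-fold. In the same kind of sum for the adult libraries the earlier profile of the same cell type took 91.1% to 94.4% of the weights. It took 70.4% in ER- luminal pregnancy and 73.8% in basal pregnancy, against 36.8% here. Both of those pregnancy sums used the ER+ luminal pregnancy library as a component. A weight fell below 0 in ER- luminal adult (-0.048) and in basal adult (-0.007). The largest misses were 1.11-fold in ER- luminal pregnancy, 1.17 in ER+ luminal adult, 1.28 in basal adult, 1.5 in basal pregnancy and 2.41 in ER- luminal adult. A change of ER+ luminal cells in pregnancy towards the other profiles may give the same values and was not tested, and with 1 library it cannot be separated from a mixed sort.

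Most regions called between pregnancy and adult with all 9 libraries were lower in pregnancy, in the 3 shallowest libraries, whereas without the basal adult library 27 were higher and 29 lower. The 2080 regions called lower had a median log2 difference of -1.52 (quartiles -1.86 to -1.20, median SE 0.33) in the deposited values. At equal depth it was -1.37 (-1.73 to -1.02, SE 0.36), where the median of all regions was 0.22. The regions were chosen on the same reads, and random thinning hardly moves the expected ratio of bright regions whatever the cause. The value at equal depth thus cannot decide whether depth is a cause. After quantile normalization the median was -1.28 (-1.78 to -0.84, SE 0.32). Equalising the range of values thus removed only part of the difference in these regions, which were chosen on the deposited values. Of these regions 509 were called again at equal depth and 835 after quantile normalization; the 1571 and 1245 that were not had smaller differences, with medians of -1.26 and -0.99, and at equal depth the SE also grew. Depth and value range may therefore add to the number of calls, and thinning does not equalise library quality. A batch that followed the stages is not given in the labels and would be confounded with them, so a biological change of stage stays open and untested.

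Some regions were open or closed together in the 3 libraries of 1 stage. In 20 regions the lowest pregnancy value was at least 8 times the highest of the other 6 libraries and at least 20. In 1 region, merged31812, the reverse held, and puberty and adult had 0 such regions. Of these 21 regions 14, or 66.7%, had a neighbouring number in the same class, against at most 2 in 10000 random draws and 0 of 47 regions set apart in the same way in 1 cell type. The 14 regions lie close together by number, around merged15134 and merged15145, so they may count as 1 event. The random draws took regions as independent, so they do not measure support for a cause. A difference in the DNA of the mice used for pregnancy, such as a haplotype or an inserted or copied segment, is a candidate explanation, and a chromatin change of 1 domain in the 3 cell types stays open, since the regions carry no coordinates. Both readings assume that neighbouring numbers lie next to each other in the genome, which could not be checked.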

How the results depend on the processing

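The alternatives with thinned reads, edgeR, DESeq2 or fewer cell types, and those for the region sets, were chosen after the data had been seen. Over 32 results and 305 recomputed values, 205 stayed within 1.5 times the reported value and 100 moved further. This leaves out median-of-ratios scaling, which moved no value. Of the 72 values that carry a sign, the medians of the region sets, 0 reversed. The side with more regions turned in 22 of 189 counts with directions. For pregnancy against adult and against puberty it turned with cell type left out and without a variance trend, and for the latter at equal depth with a pseudocount of 1 read (1841 higher and 1667 lower). For ER+ against ER- luminal it turned after quantile normalization (14488 higher and 15858 lower), at equal depth with it (9401 and 11084) and without the ER+ luminal puberty (7277 and 8296) or adult library (5972 and 7330). For ER+ luminal against basal it turned with a pseudocount of 4 (23898 and 23837) and without the ER+ luminal pregnancy library (29522 and 29242). Within cell types it turned from adult to pregnancy after quantile normalization in basal (6456 and 3871 became 4158 and 5102), ER- luminal (4356 and 1923 became 2947 and 3228) and ER+ luminal cells (13802 and 8343 became 9108 and 10000), and with a pseudocount of 4 in ER- luminal (314 and 365) and ER+ luminal cells (3535 and 4802). From puberty to pregnancy it turned after quantile normalization in basal (4722 and 3230 became 4396 and 4741) and ER+ luminal cells (15395 and 7887 became 9322 and 9729), and in the latter with a pseudocount of 4 (4567 and 4675). From puberty to adult it turned in basal cells (2211 and 2911) with a pseudocount of 4 (293 and 107), without the lowest 25% of regions (1044 and 994) and after quantile normalization (2664 and 2144). For every change below the cause was not tested. Leaving out a library or regions leaves less to test, yet the calls did not always fall. Without the ER+ luminal pregnancy library they rose to 47963 for ER+ against ER- luminal. No region called in a comparison was called with the opposite sign under any alternative. The variance shares all stayed within 1.5 times. The gene lists, motifs and promoter share were not run. With a pseudocount of 4 the calls were 4 for adult against puberty. With a pseudocount of 0.25 the calls were 1469 for pregnancy against adult, 4378 for pregnancy against puberty and 2079 for any stage difference. After quantile normalization the calls were 1218 for pregnancy against adult, 2835 for pregnancy against puberty and 1480 for any stage difference. With the other factor left out of the model the calls were 9366 for ER- luminal against basal, 14 for pregnancy against adult, 22 for pregnancy against puberty, 1 for adult against puberty and 18 for any stage difference. With library weights the calls were 59623 for ER+ against ER- luminal, 28626 for ER- luminal against basal, 360 for adult against puberty and 6914 for any stage difference. Without a variance trend the calls were 8466 for ER- luminal against basal, 26 for pregnancy against adult, 30 for pregnancy against puberty, 0 for adult against puberty and 25 for any stage difference. In the 6 compared libraries alone the calls were 27001 for ER- luminal against basal and 6 for adult against puberty. At equal depth the calls were 20739 for ER+ against ER- luminal, 10515 for ER- luminal against basal, 608 for pregnancy against adult and 1791 for pregnancy against puberty. At equal depth with quantile normalization the calls were 20485 for ER+ against ER- luminal, 753 for pregnancy against adult and 1448 for pregnancy against puberty. At equal depth with a pseudocount of 1 read the calls were 1126 for pregnancy against adult and 3508 for pregnancy against puberty. With edgeR the calls were 1003 for pregnancy against adult. With DESeq2 the calls were 10 for adult against puberty. In the ER- luminal and basal libraries alone the calls were 857 for pregnancy against adult, 1413 for pregnancy against puberty and 11 for adult against puberty. Thinning shifted the median log2 difference of all regions to 0.22 for pregnancy against adult and to 0.27 for pregnancy against puberty, so calls between stages at equal depth are relative to a moved centre.

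Leaving out each library in turn gave 12326 to 47963 for ER+ against ER- luminal, 23589 to 58764 for ER+ luminal against basal, 5295 to 27161 for ER- luminal against basal, 56 to 3268 for pregnancy against adult, 80 to 8101 for pregnancy against puberty, 1 to 13 for adult against puberty, 34147 to 69175 for any cell type difference and 649 to 5051 for any stage difference. A group that lost its library then had fewer libraries than the group it was compared with.

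Untested counts of regions that differed at least 4-fold within a cell type depended on low values throughout. With a pseudocount of 4 they were 2088 (basal), 679 (ER- luminal) and 8337 (ER+ luminal) from adult to pregnancy, 1316 (basal), 2710 (ER- luminal) and 9242 (ER+ luminal) from puberty to pregnancy and 400 (basal), 446 (ER- luminal) and 751 (ER+ luminal) from puberty to adult. With a pseudocount of 0.25 they were 9752 (ER- luminal) from adult to pregnancy and 9688 (basal), 9614 (ER- luminal) and 10835 (ER+ luminal) from puberty to adult. Without the lowest 25% of regions they were 5008 (basal) and 2963 (ER- luminal) from adult to pregnancy, 3591 (basal) and 6181 (ER- luminal) from puberty to pregnancy and 2038 (basal), 2463 (ER- luminal) and 2356 (ER+ luminal) from puberty to adult. After quantile normalization they were 2536 (ER+ luminal) from puberty to adult. At equal depth they were 17845 (basal) and 13207 (ER- luminal) from adult to pregnancy, 14894 (basal) and 20060 (ER- luminal) from puberty to pregnancy and 14374 (basal), 15078 (ER- luminal) and 13375 (ER+ luminal) from puberty to adult. Of the medians of the region sets, the ER- luminal-closed set in pregnancy moved, from -0.55 to -0.90 with a pseudocount of 4. Depth limits the pregnancy libraries most, where 3 reads are worth 4.55 to 6.60 units.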

Other observations

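The splits of the libraries below were set before their results were seen, and the change correlations were computed after. When the 6 libraries of a comparison were divided in the 10 possible ways, only the real division gave as many calls: 1 of 10 in each of the 6 comparisons. The highest other division called 0 regions against 32576, 44646, 17510, 2325 and 6656, and 1 region against the 2 between adult and puberty, and 10 divisions are too few for a share under 0.05. With labels exchanged within stages, 1 of 36 arrangements, the real one, called 53921 regions for any difference between cell types and the highest other called 7459, so a chance arrangement is excluded at that level. With labels exchanged within cell types, 1 of 36, the real one, called 3705 regions for any stage difference and the highest other called 3384. Arrangements that exchanged only puberty and adult labels, and so kept the pregnancy libraries together, called 2342, 2564 and 3384. Those that moved a pregnancy label called at most 1 region. The rank thus rests on pregnancy against the earlier stages and does not exclude a chance arrangement of puberty and adult labels. The arrangements were not repeated under other settings.

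Changes from adult to pregnancy were weakly shared between cell types. Across 62430 regions at or above the median, which are not independent replicates, the log2 changes correlated at 0.32 between basal and ER- luminal cells, 0.24 between basal and ER+ luminal cells and 0.17 between the luminal types. From puberty to adult the values were 0.12, 0.17 and 0.25. Region merged51739 was the brightest and took 0.221% to 1.159% of the reads in a library, most in ER- luminal pregnancy.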
